A study of Homo sapiens with 2 samples.

How the data were processed

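RNA was measured in OVSAHO, an established human cell line from a serous ovarian cancer. There were 2 libraries, 1 per group. In the perturbed group, per the submitters' series title and design text, expression of the chromatin-remodelling ATPase SMARCA2 was raised and its paralog SMARCA4 was lowered. The genotype label gives SMARCA2 as stable and SMARCA4 as knocked down. The control group had neither change. Both cultures were kept in 25 µM carboplatin, a platinum drug that crosslinks DNA, for 2 days before RNA was taken. Groups were taken from the genotype labels. Per the labels' protocols, total RNA was purified with a Qiagen micro-scale kit, cDNA was made with the SMART-Seq HT kit, and libraries were made with Nextera XT. SMART-Seq primes cDNA from the poly(A) tail, amplifies it by PCR and does not mark strand, so a gene and an antisense partner cannot be told apart.

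Each library came with a deposited table of FPKM (fragments per kilobase of transcript per 1000000 mapped fragments), 1 value for each of 26255 gene symbols, per the file headers. No symbol was listed more than once in a table. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 and the build hg19. The gene annotation, the filters, the treatment of reads that map to several places and any scaling between the libraries are not given in the sources used here. The annotation at hand was GENCODE 29 on GRCh38, another build, so no coordinates are reported. Only its transcript names, lengths and base composition were used, for transcripts that it matches to RefSeq (93.1% of the measured genes).

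The depth was estimated from the steps of low values. Among the 1129 genes above 0 in both libraries and under 0.3 FPKM, 78.6% had a ratio that matched whole fragments, 1 to 8 in each library, within 0.002 on the log2 scale. The mean share at random offsets was 1.67%. A fragment was worth 1.02 times as much FPKM in the perturbed library as in the control. The value of a fragment followed an effective length shorter than the transcript. Over genes with a single matched transcript of at least 300 bases, the depth and the shortening were chosen jointly so that the most values above 0 lay in a window 2% wide at the value of 1 fragment. This gave a shortening of 200 bases and about 8850000 fragments behind the perturbed FPKM and 9050000 behind the control. At this depth, 1 FPKM of a 2 kb transcript was about 15.9 fragments. Approximate fragment numbers per gene were made from FPKM, the shortened length and these depths, for transcripts of at least 300 bases only, and 95% intervals of a fold are exact binomial (Clopper-Pearson) intervals on them. These intervals cover counting error alone. PCR copies are not independent molecules and the lengths may differ from those the authors used, so they are too narrow as a statement about cultures.

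With 1 library per group, no p-value, standard error or adjusted p can be given for any gene, and none was computed. Genes were described by a rule of size fixed before the data were examined. A gene was called higher or lower when it was at 1 FPKM or more in at least 1 library and log2((FPKM + 1) / (FPKM + 1)), perturbed over control, was at least 1 or at most -1. The pseudocount of 1 FPKM understates the change of weakly expressed genes. Folds in the text are ratios of the deposited FPKM without the pseudocount, and log2 ratios include it.

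The 36 gene lists, the rule and the alternatives were also fixed before the data were examined, from textbook knowledge of chromatin remodelling, platinum response and ovarian cancer. For each list the median log2 ratio over its measured members was set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile among them describes these 2 libraries and is not a test of the conditions. Lists with fewer than 5 measured members got no percentile. All list members were found in the tables by symbol or by an older or newer name.

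The genes named were fixed by rule: SMARCA2, SMARCA4, ACTB and GAPDH; the 12 largest ratios in each direction among genes above 0 in both libraries and at 10 FPKM or more in the higher, leaving out uncharacterized loci, microRNAs and most small RNAs; up to 5 genes per direction listed at 0 in the other library; and up to 4 members per direction of each list past the rule of size, or the 2 most abundant measured members where none passed. A few other list members are given with their values because the list cannot be described without them; these were chosen after their values were seen. A few genes that the rule names are not reported here.

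Alternatives were another pseudocount (0.1 or 5 FPKM), scaling each library to a sum of 1000000, centring on the median ratio, a trimmed mean of ratios (30% of ratios and 5% of levels), other filters (none, 5 FPKM in a library, 1 FPKM in both) and other rules of size (1.5-fold or 4-fold). After the data were seen, a cubic trend of the ratio on log2 transcript length, GC content and level was removed as a further alternative, over genes with a matched transcript length only, and transcripts under 300 bases were left out as another, with and without the genes that had no matched length. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedure was tested on simulated data made from the control library with 200 genes changed 4-fold or 8-fold and noise of 0.3 (SD, log2). It recovered 100% of the changed genes at each fold, and 0.028% of unchanged genes passed the rule at 4-fold. The changed genes were drawn from those at 5 FPKM or more in the control and the noise was assumed, so these shares largely follow from the settings. Between the 2 libraries the SD of the log2 ratio was 0.55 to 0.88 by bin of level, with any real changes included. The simulated shares are therefore no error rates for these data. The depth estimate was tested on simulated fragments from 11323 genes with shortenings of 100 and 200 bases, and it found both.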

Results

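The study asked how the transcriptome of carboplatin-treated OVSAHO ovarian cancer cells differs when the balance of the SWI/SNF ATPases is shifted from SMARCA4 to SMARCA2. RNA-seq was available for 1 perturbed culture and 1 control culture, each after 2 days in 25 µM carboplatin. The perturbed library had 15925 genes above 0 and 11271 at 1 FPKM or more. The control library had 15517 and 10730. The estimated depths were 8850000 and 9050000 fragments. The 100 most abundant genes took 35.5% of the perturbed FPKM and 34.5% of the control FPKM, and FTH1, the ferritin heavy chain, was the most abundant in each. There were no replicates, so no value below has a between-culture error, and each difference is between these 2 libraries, or between 2 clones if the numbers in the sample titles mark clones, which the labels do not state.

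The perturbed genes came first, as a check of the labels. SMARCA2, a catalytic ATPase of the SWI/SNF complex, was at 2.60 FPKM in the perturbed library and 0.205 FPKM in the control, 12.7-fold higher (95% counting interval 6.66 to 27.1). SMARCA4, the alternative ATPase of the same complex, was at 4.49 FPKM against 27.9 FPKM, 6.21-fold lower (5.37 to 7.20). Both went the way the submitters' series text states, and the genotype label itself gives a direction for SMARCA4 alone. SMARCA2 stayed below SMARCA4 in the perturbed library all the same, and the fragments behind it were few, about 124 against 10 in the control. GAPDH was at 4067 and 4310 FPKM, and ACTB at 2339 and 3257 FPKM.

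Of 11785 genes at 1 FPKM or more in at least 1 library, 925 were higher and 897 were lower in the perturbed library, and 9963 lay within 2-fold. The correlation of log2 levels across these genes, which are not independent replicates, was 0.94. The genes at 1 FPKM or more in both libraries had a median log2 ratio of -0.11 without the pseudocount. All measured genes had a median of -0.06 with it, and ratios near 0 below are to be read against these medians. This was not 1 common shift of scale: the median was 0.14 at mean levels of 1 to 5 FPKM and -0.28 at 50 to 200 FPKM. Centred on the median of -0.11, 1200 genes were higher and 652 lower, which moved the share of higher genes among those past 2-fold from 50.8% to 64.8%. That centre came from ratios without the pseudocount. It was subtracted from ratios with the pseudocount, whose median was -0.06, so it overcorrected them. Of the higher genes with a known transcript length of at least 300 bases, 98.4% had a counting interval that excluded a fold of 1, as did 791 of the 811 lower ones. These genes were chosen by the size of the same ratios, so such shares follow largely from the choice.

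**Figure D1:**
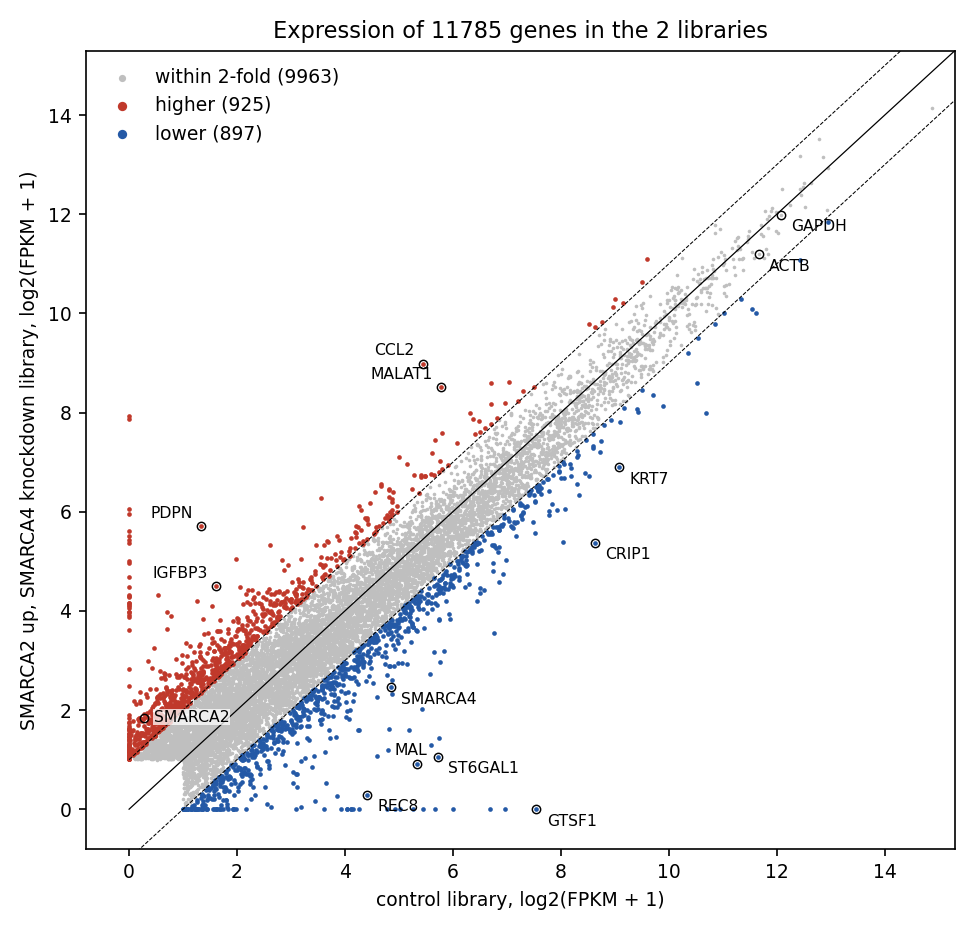
Log2(FPKM + 1) of the 11785 measured genes in the control library (x axis) and the perturbed library (y axis), 1 point per gene. Dashed lines mark the 2-fold rule; 925 genes lay above them and 897 below, with SMARCA2 on the higher side and SMARCA4 on the lower.

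Among genes above 0 in both libraries, PDPN, the membrane glycoprotein podoplanin, was at 51.1 FPKM against 1.51, 33.8-fold higher (22.4 to 54.9). The monocyte chemokine CCL2 was at 507 FPKM against 42.5, 11.9-fold higher (10.4 to 13.8). The matrix protein SPARC was 12.3-fold higher (9.15 to 17.3), the secreted protease HTRA1 17.9-fold, and IGFBP3, which binds insulin-like growth factors, 10.4-fold (7.08 to 16.3). The carboxypeptidase CPVL (42.4-fold), alkaline phosphatase ALPL (32.3 against 2.94 FPKM), CCDC146 (19.7-fold), TMEM100 (8.44-fold) and the chromatin protein MPHOSPH8 (6.81-fold) were also among the 12 largest. The nuclear long non-coding RNA MALAT1 was at 365 FPKM against 53.7, 6.80-fold higher. The read-through locus BLOC1S5-TXNDC5 was 23.1-fold higher, an uncertain value because it shares exons with its parent genes.

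The largest decreases included ST6GAL1, a Golgi sialyltransferase, at 1.08 FPKM against 51.7, 47.7-fold lower (35.1 to 68.0). The membrane proteolipid MAL was 44.2-fold lower (19.1 to 141). The meiotic cohesin subunit REC8 was at 0.223 FPKM against 20.3, 91.0-fold lower (37.1 to 353). The long non-coding RNA UCA1 (30.8-fold), MYEOV (20.9-fold), BEX5 (17.6-fold), MLLT11 (21.1-fold) and PPP1R14A, an inhibitor of myosin phosphatase (68.5-fold), were lower as well. The PPP1R14A value rested on about 0.881 fragments, that is a single fragment, in the perturbed library, with an interval of 10.5-fold to 2434-fold. The cytidine deaminase APOBEC3B was 13.8-fold lower (9.53 to 20), the LIM-domain protein CRIP1 9.77-fold (7.97 to 12.1) at 395 FPKM in the control, and the tubulin TUBA4A 9.95-fold (8.62 to 11.6). TMEM189-UBE2V1, 32.2-fold lower, is a read-through locus with the same uncertainty.

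Some genes were listed at 0 in only 1 library. GTSF1, a germline factor of the piRNA pathway, was at 186 FPKM in the control and at 0 in the perturbed library. CGA, the alpha subunit of the glycoprotein hormones, was at 26.3 FPKM and 0, the cancer-testis genes PAGE5 and BAGE at 3.47 and 2.95 FPKM and 0, and SNHG25 at 29.4 FPKM and 0. In the other direction, RARRES2, which encodes chemerin, was at 6.07 FPKM and PCOLCE2 at 2.72 FPKM in the perturbed library, each with 0 in the control. The small Cajal body RNAs SCARNA22, SCARNA15 and SCARNA23 were at 234, 18.4 and 16.9 FPKM against 0. Such short transcripts can reach this FPKM from about 1 fragment: SNORA9 and SNORA15 were both at 15.6 FPKM in the perturbed library, and SNORA10 and SNORA21 both at 31.2 FPKM, 2 times that. The values of SCARNA15, SCARNA23 and SNHG25, also a short transcript, can therefore rest on 1 fragment or a few, and a 0 in the other library says little.

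Of 23 measured SWI/SNF subunits, 5 were higher and 2 lower. The lower ones were SMARCA4 itself and ACTL6A, an actin-related subunit, at 91.0 FPKM against 188. The higher ones, besides SMARCA2, were the DNA-binding subunits ARID1A (6.97-fold, 6.70 against 0.961 FPKM) and ARID2 (5.33-fold), the bromodomain subunit BRD7 (3.23-fold) and the core subunit SMARCC1 (8.77 against 3.48 FPKM). The list's median log2 ratio was 0.42, at percentile 99.9 of the matched random lists. ARID1A and ARID2 have long transcripts, a class with higher ratios. With trends on transcript length, GC content and level removed, 3 subunits were higher and 1 lower, with a median of 0.39 at percentile 99.8. With genes at 1 FPKM or more in both libraries, the median was 0.17 at percentile 97.0, inside the range of random lists.

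Target genes of the YAP and TAZ coactivators had the largest median of the lists with at least 5 measured members. Of 17 measured genes, 10 were higher, 1, ANKRD1 at 1.15 against 3.61 FPKM, was lower, and 11 had a ratio above 0. IGFBP3 led, followed by the YAP partner TEAD1 (6.71-fold, 3.86 against 0.575 FPKM), the phosphatase PTPN14 (4.11-fold) and the matricellular factor CTGF (2.85-fold, 57.4 against 20.2 FPKM). CYR61 and AMOTL2, widely used target genes, were at 102 and 121 FPKM and at 35.2 and 61.8 FPKM. The median was 1.05, at percentile 100. Among the 10 members at 5 FPKM or more in a library the median was 0.40, just inside the central 95% of random lists. Members of that group went apart: IGFBP3, CTGF and PTPN14 were higher, and CYR61 and AMOTL2 were not. With trends on transcript length, GC content and level removed, the median was 0.75, and 3 of the 17 were higher by the rule and 1 lower.

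Mesenchymal genes had 5 higher and 2 lower of 15 measured, with a median of 0.71 at percentile 99.5. SPARC, the smooth-muscle actin-binding protein TAGLN (3.51-fold, 174 against 49.5 FPKM), the collagen COL6A2 (5.58-fold) and the transcription factor TWIST2 (4.36-fold) were higher. The transcription factor SNAI1 (2.53-fold) and the surface protein THY1 (4.11-fold) were lower. Vimentin, VIM, was at 342 and 313 FPKM. The median depended on the filter and the pseudocount. It was 1.53 at percentile 100 among the 7 members at 5 FPKM or more in a library, 0.13 at percentile 72.8 among the 9 at 1 FPKM or more in both, 0.22 at percentile 94.1 with a pseudocount of 5 FPKM, and 0 at percentile 32.9 without a filter. With trends removed it was 0.38 at percentile 97.54, barely above the central 95% of random lists.

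Epithelial genes went both ways, with 2 higher and 5 lower of 17 and a median of -0.26 at percentile 15.2. The keratin KRT7 was 4.55-fold lower (4.31 to 4.80; 119 against 540 FPKM), and the epithelial transcription factor ELF3 (6.25-fold), the protease inhibitor SPINT1 (5.32-fold) and the tight-junction claudin CLDN4 (3.98-fold) were lower. Desmoplakin, DSP (3.67-fold), and CLDN3 (2.09-fold) were higher, and the cadherin CDH1 was at 3.52 and 3.40 FPKM. Genes of high-grade serous ovarian carcinoma had 4 higher and 1 lower of 18, with a median of 0.11 at percentile 91.5. Among the 15 members at 5 FPKM or more in a library the median was 0.74 at percentile 100, outside the central 95% of random lists. The kallikreins KLK10 (5.49-fold) and KLK8 (2.37-fold) and the lineage factor WT1 (3.61-fold) were higher and KLK6 (2.17-fold) was lower. Of 11 measured stem-cell-associated genes, SOX2 (9.96-fold, 5.71 against 0.573 FPKM) was higher and THY1 lower, with a median of 0.35 at percentile 84.5, and at percentile 97.6 with a pseudocount of 5 FPKM.

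FGF receptors, ligands and ERK feedback genes had 4 higher and none lower of 19. The ligand FGF18 (4.63-fold, 19.5 against 4.22 FPKM), the receptor FGFR1 (2.63-fold, 2.24 to 3.10; 13.3 against 5.08 FPKM) and the feedback inhibitors SPRY1 (4.33-fold) and SPRY4 (2.75-fold) were higher. FGFR2 was at 4.53 and 4.60 FPKM and DUSP6 at 8.83 and 7.30 FPKM. The list's median was 0.25, at percentile 90.2. Wnt genes had 2 higher, LEF1 (2.03 against 0.0452 FPKM) and ZNRF3 (7.35-fold), and 1 lower, the secreted inhibitor DKK1, of 10. DKK1 was 13.4-fold lower (4.27 to 67.5), on about 2.97 fragments in the perturbed library, and LEF1 rested on about 0.851 in the control. The Wnt list's median was 0.54 at percentile 97.4. The percentile was 99.7 with a pseudocount of 5 FPKM, 98.1 with FPKM scaled to a common sum and 99.6 with trends removed, each outside the central 95% of random lists. None of 15 TGF-beta target genes passed the rule, with ID1 at 654 and 472 FPKM, ID3 at 414 and 278 FPKM and a median of -0.14 at percentile 27.9. Among the 9 members at 5 FPKM or more in a library it was 0.40 at percentile 97.8, outside the central 95% of random lists.

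**Figure D2:**
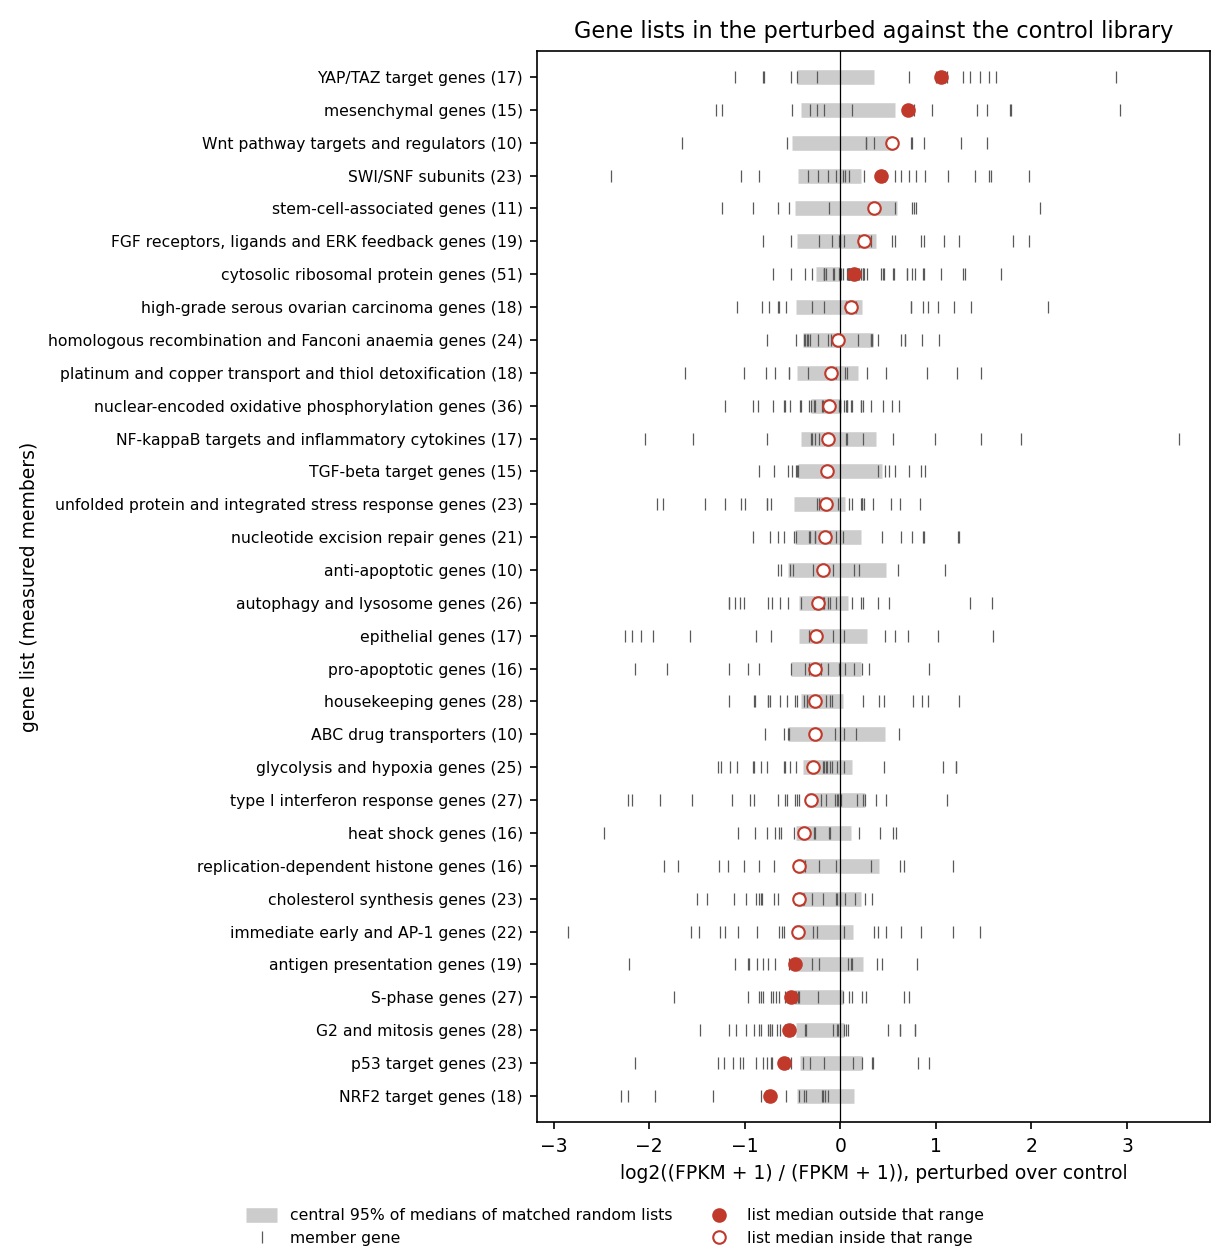
Log2((FPKM + 1) / (FPKM + 1)), perturbed over control (x axis), for the 32 gene lists with at least 5 measured members (y axis). Ticks are member genes, circles are list medians and grey bars hold the central 95% of medians of 10000 matched random lists; 4 medians lay above their bar and 5 below (filled circles).

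For genes tied to platinum response, no ABC drug transporter passed the rule among 10 measured. ABCB6 was at 14.9 and 26.5 FPKM and ABCB8 at 16.9 and 15.0 FPKM, and the median was -0.27 at percentile 19.4. The multidrug transporter gene ABCB1 was at 0.05 and 0.0245 FPKM, near the limit of what this depth can show. Genes of platinum and copper transport and thiol detoxification had 2 higher and 2 lower of 18, with a median of -0.10 at percentile 60.7. The metal-binding metallothioneins MT1X (2.79-fold, 288 against 103 FPKM) and MT1F (2.35-fold) were higher, and the copper transporter SLC31A2 (3.63-fold) and the glutathione transferase GSTM1 (2.14-fold) were lower. Homologous recombination and Fanconi anaemia genes had 1 higher of 24, BRCA1 (2.65-fold, 4.62 against 1.74 FPKM), and none lower, with a median of -0.02 at percentile 51.4. With trends on transcript length, GC content and level removed, BRCA1 lay within 2-fold, at a log2 ratio of 0.78. None of 23 was then higher and 1, FANCM, was lower, with the list at percentile 63.3. Nucleotide excision repair genes had 2 higher of 21, ERCC1 (2.38-fold, 87.4 against 36.7 FPKM) and ERCC2 (3.25-fold), and none lower, with a median of -0.16 at percentile 47.7.

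Target genes of the tumour suppressor p53 were lower as a list, with 6 lower and none higher of 23 and a median of -0.58 at percentile 0.17. PMAIP1, which encodes the pro-apoptotic protein NOXA, was 4.59-fold lower (19.5 against 89.6 FPKM), and TP53INP1 (4.75-fold), CCNG1 (2.48-fold) and the kinase PLK3 (2.25-fold) were lower. The cell-cycle inhibitor CDKN1A was at 41.2 against 86.4 FPKM and BAX at 89.8 against 46.6 FPKM. With the trends on length, GC and level removed, 3 of the 23 were past the rule and the median was -0.55 at percentile 0.14. Pro-apoptotic genes had 3 lower and none higher of 16, among them PMAIP1 and BAK1 (2.25-fold), with a median of -0.26 at percentile 30.2. Of 10 anti-apoptotic genes, the caspase inhibitor XIAP (3.89-fold, 2.55 against 0.656 FPKM) was higher and none was lower, with a median of -0.18 at percentile 31.7. XIAP has a long transcript, and with the trends removed it lay within 2-fold, at a log2 ratio of 0.65. None of the 10 was then higher and 1, BCL2, was lower, with the list at percentile 57.2. BCL2L1 was at 34.0 and 22.0 FPKM and MCL1 at 14.4 and 12.5 FPKM.

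Of 27 S-phase genes, 20 had a ratio below 0 and 1 passed the rule, the cyclin CCNE2 (3.54-fold lower), with a median of -0.51 at percentile 1.60. Of 28 G2 and mitosis genes, 20 had a ratio below 0 and 3 passed, the kinases NEK2 (2.84-fold) and AURKA (2.26-fold) and the centromere protein CDCA8 (2.15-fold), with a median of -0.54 at percentile 0.58. The proliferation marker MKI67 and the centromere protein CENPF, both long transcripts, were at 26.0 against 14.7 FPKM and at 16.8 against 9.32 FPKM. With the trends on length, GC and level removed, neither list stood apart: the medians were -0.28 at percentile 7.08 and -0.22 at percentile 14.1.

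Targets of the oxidative-stress factor NRF2 had the lowest median of the lists with at least 5 measured members, -0.73 at percentile 0, and all 18 measured members had a ratio below 0, 4 of them lower by the rule and 14 within 2-fold. The aldo-keto reductases AKR1C3 (10.7-fold, 0.677 against 7.24 FPKM) and AKR1B10 (8.13-fold), OSGIN1 (3.90-fold, 46.7 against 182 FPKM) and sulfiredoxin, SRXN1 (2.58-fold), were the lower ones. The quinone reductase NQO1 was at 78.4 and 131 FPKM. FTH1 and FTL, the ferritin chains, were at 18222 and 30274 FPKM and at 4373 and 7775 FPKM. Heat shock genes had 2 lower of 16, the small chaperones CRYAB (6.13-fold) and HSPB1 (2.11-fold, 885 against 1863 FPKM), with a median of -0.38 at percentile 6.60. Unfolded protein and integrated stress response genes had 5 lower and none higher of 23, among them the amino acid transporter subunit SLC3A2 (3.78-fold, 388 against 1470 FPKM), DNAJB9 (3.88-fold), PPP1R15A (2.74-fold) and ATF3 (2.41-fold), while HSPA5 was at 195 and 198 FPKM. That list's median was -0.15 at percentile 70.1. Autophagy and lysosome genes had 2 higher, ULK1 (4.53-fold) and LAMP1 (2.73-fold), and 5 lower, among them GABARAPL1 (2.36-fold), NEU1 (2.25-fold) and LAMP2 (2.18-fold), of 26, with a median of -0.23 at percentile 32.6.

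Antigen presentation genes had 2 lower and none higher of 19, with a median of -0.47 at percentile 1.97. The invariant chain CD74 was 8.37-fold lower (0.964 against 8.07 FPKM), the peptide transporter TAP1 2.17-fold lower, and B2M was at 1108 and 1876 FPKM. With a pseudocount of 5 FPKM the percentile was 4.80, and over the 17 members at 1 FPKM or more in both libraries it was 3.06, both inside the central 95% of random lists. Type I interferon response genes had 5 lower and 1 higher, STAT2 (2.47-fold), of 27, with a median of -0.30 at percentile 4.70. The percentile was 0.83 with a pseudocount of 0.1 FPKM, 2.04 with FPKM scaled to a common sum and 2.41 with trends removed, each outside the central 95% of random lists. IRF9, the DNA-binding partner of STAT2, was 5.20-fold lower (6.65 against 34.6 FPKM), and IFI27 (4.66-fold), IFITM1 (3.75-fold) and IFIT5 (4.53-fold) were lower, while IFITM3 was at 2472 and 2451 FPKM. NF-kappaB targets and inflammatory cytokines had 3 higher, CCL2, CXCL1 (3.83-fold, 93.9 against 24.5 FPKM) and NFKB1 (3.84-fold), and 2 lower, CXCL8 (17.9-fold, 0.225 against 4.04 FPKM) and IL6 (7.09-fold), of 17, with a median of -0.12 at percentile 33.5. Immediate early and AP-1 genes had 6 lower and 2 higher of 22, with a median of -0.44 at percentile 4.92, and at percentile 2.38 with a pseudocount of 5 FPKM and 2.14 with at least 5 FPKM in a library. FOSL1 (8.31-fold, 5.65 against 46.9 FPKM), FOS (3.20-fold), NR4A1 (2.88-fold) and NR4A2 (2.88-fold) were lower, and JUND (2.45-fold) and CTGF were higher.

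Cholesterol synthesis genes had 3 lower and none higher of 23, among them the epoxidase SQLE (2.99-fold, 11.7 against 34.8 FPKM) and IDI1 (2.68-fold), with a median of -0.43 at percentile 3.19, and at percentile 1.72 with a pseudocount of 5 FPKM and 2.15 without a filter. Glycolysis and hypoxia genes had 3 higher, NDRG1 (2.53-fold), EGLN3 (2.94-fold) and PFKL (2.15-fold), and 4 lower, ALDOC (2.46-fold), ANKRD37 (2.66-fold), PFKFB3 (2.45-fold) and BNIP3 (2.13-fold), of 25, with a median of -0.29 at percentile 8.84. With trends removed it was -0.40 at percentile 0.505, outside the central 95% of random lists. Nuclear-encoded oxidative phosphorylation genes had 1 lower of 36, NDUFS1 (2.40-fold), with a median of -0.12 at percentile 61.5.

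Among control lists, cytosolic ribosomal protein genes had 4 higher and none lower of 51, with a small median of 0.14 at percentile 100. The higher ones included RPL13A (3.23-fold), RPL22 (2.49-fold) and RPS12 (2.44-fold), and these genes have many processed pseudogenes that can share their reads. Housekeeping genes had a median of -0.27 at percentile 20.6, with GUSB (2.40-fold) higher and EMC7 (2.25-fold) lower of 28. Replication-dependent histone genes, near-identical copies whose mRNA mostly lacks a poly(A) tail, had 1 higher, HIST1H1E (2.81-fold), and 5 lower of 16, with a median of -0.43 at percentile 3.32. That list lay outside the central 95% of random lists under 4 of the 10 alternatives, and some of the 10 cannot change a percentile. The 4 included trends removed, with a median of -0.66 at percentile 0.04. The lower ones included HIST1H2AG (4.73-fold), HIST1H2BD (4.04-fold), HIST1H2AC (2.29-fold) and HIST1H4B (1.42 FPKM in the control and 0 in the perturbed library). The HIST1H4B value rested on about 3.05 fragments in the control, so counting error alone does not exclude equal levels. Markers of other cell types were mostly under 1 FPKM. Of 12 fibroblast markers 2 were at 1 FPKM or more in a library, THY1 and FBLN1 at 39.6 and 20.5 FPKM, and COL1A1 was at 0.0985 and 0.154 FPKM. Of 17 blood cell markers 3 were measured, with CD68, a lysosomal protein, at 11.1 and 34.9 FPKM, and PTPRC was at 0 in both libraries. Of 11 endothelial markers 1 was measured, ESAM at 0.474 and 3.71 FPKM. Of 16 neuronal markers 4 were measured, with TUBB3 at 28.1 and 46.4 FPKM and INA at 8.42 and 17.8 FPKM.

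Of the 32 lists with at least 5 measured members, 4 had a median above the central 95% of random lists and 5 below. By chance 1.6 lists in all would fall outside if the members of a list varied as independently as randomly drawn genes. Members of a list can vary together between any 2 cultures, which that figure leaves out. With trends removed, 11 lists lay outside: the S-phase and the G2 and mitosis lists came inside, and the Wnt, interferon, glycolysis and hypoxia, and histone lists went outside.

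The ratio between the libraries went with properties of the transcripts. In the decile of genes with the longest transcripts (median 7193 bases) the median log2 ratio was 0.42, with 16.8% of genes higher and 2.00% lower. In the decile around 2363 bases it was -0.22. By level, it was 0.38 in the least abundant decile and -0.29 in the decile around 73.7 FPKM. Spearman's rho across 10972 genes, which are not independent, was 0.16 with length, 0.06 with GC content and -0.25 with level. Among the 10972 genes with a matched transcript length, 845 were higher and 823 lower as deposited, and 631 and 804 with these trends removed.

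**Figure D3:**
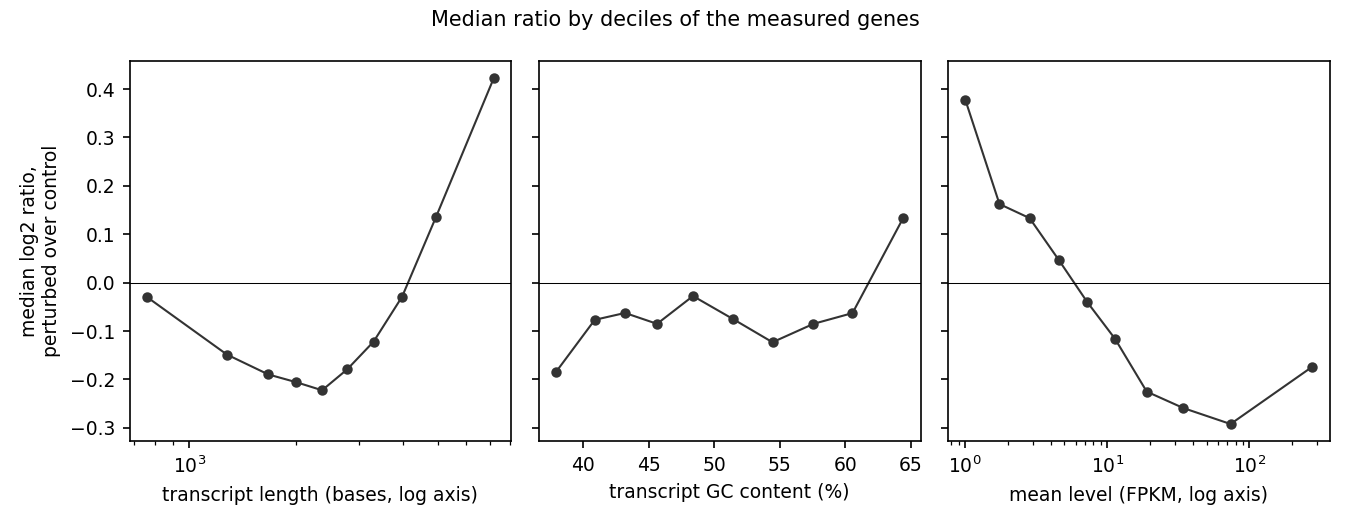
Median log2 ratio of the perturbed over the control library (y axis) in deciles of the measured genes by transcript length in bases, GC content in percent and mean level in FPKM (x axes; length and level on log axes). Each point is the median of about 1097 genes; the longest decile lay at 0.42 and the least abundant decile at 0.38.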

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

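The removal of trends and the limit on short transcripts were chosen only after the results were seen; the other alternatives were not. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. No symbol had more than 1 value, so that choice moved nothing, and dropping the filter cannot change the counts of genes. The p53, NRF2 and ribosomal protein lists lay outside the central 95% of random lists under all 10 alternatives. Of these 10, the centring, the trimmed mean and the choice among repeated symbols could not change the percentile of any list. SMARCA2 had a log2 ratio of 3.15 with a pseudocount of 0.1 FPKM and 0.55 with 5 FPKM, and SMARCA4 of -2.61 and -1.79, since the pseudocount damps low values. Genes higher in the perturbed library numbered 1630 with a pseudocount of 0.1 FPKM, 219 with 5 FPKM, 546 with at least 5 FPKM in a library, 557 with at least 1 FPKM in both, 2253 by a 1.5-fold rule and 71 by a 4-fold rule. Lower genes numbered 380 with a pseudocount of 5 FPKM, 2505 by a 1.5-fold rule and 84 by a 4-fold rule. With transcripts under 300 bases left out, 890 genes were higher and 885 lower, and with genes without a matched length left out as well, 810 and 811. The mesenchymal median was 1.48 and 0.22 with pseudocounts of 0.1 and 5 FPKM, 0 without a filter, 1.53 with at least 5 FPKM in a library and 0.13 with at least 1 FPKM in both. The YAP/TAZ median was 0.47 with a pseudocount of 5 FPKM, 0.42 without a filter and 0.40 with at least 5 FPKM in a library. That last filter also gave 0.74 for serous carcinoma genes and 0.40 for TGF-beta targets, both above the central 95% of random lists. The stem-cell list lay just above it, at percentile 97.6, with a pseudocount of 5 FPKM. With trends removed, the medians of G2 and mitosis genes and of heat shock genes were -0.22 and -0.091. The ribosomal protein median was 0.28 with FPKM scaled to a common sum. Of the marker lists with few measured members, fibroblasts had 0.91 under both stricter filters, blood cells 0 without a filter, and endothelial cells -2.73 and -0.67 with pseudocounts of 0.1 and 5 FPKM and 0 without a filter. Apart from the pseudocounts and the filters on members, the cause was not tested. Depth limits genes near 1 FPKM, where a 2 kb transcript has about 15.9 fragments.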

Other observations

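The gene families in the first 2 paragraphs were chosen after their values were seen, and so were the tests below, except the test on nuclear RNAs. Of 11 measured S100 calcium-binding proteins, 6 were lower, 5 lay within 2-fold and none was higher, with a median log2 ratio of -1.42. S100A16 was at 40.6 against 263 FPKM, S100A4 at 1026 against 3124 FPKM and S100A6 at 1084 against 2999 FPKM, while S100A10 was at 716 against 483 FPKM and S100A13 at 1274 against 1087 FPKM. The laminin chains LAMA5 (9.17 against 1.89 FPKM), LAMC1 (16.7 against 4.31 FPKM) and LAMA1 (3.08 against 0.747 FPKM) were higher and LAMC3 (1.32 against 4.89 FPKM) was lower, of 8 measured, with a median of 0.34 at percentile 87.7, inside the central 95% of matched random lists. The collagens COL18A1 (8.33 against 2.16 FPKM) and COL4A2 (8.06 against 2.42 FPKM) were higher, of 4 type IV and XVIII collagens measured. Of 12 alpha and beta tubulins, 11 had a ratio below 0, with TUBA4A and TUBB4A (6.67 against 32.3 FPKM) lower by the rule of size and TUBA1A (53.8 against 25.1 FPKM) higher. The tubulin median of -0.49 lay at percentile 4.40, also inside that range.

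Small nucleolar and Cajal body RNAs had 27 higher and 10 lower of 59 measured. Of these, 22 were listed at 0 in the control and 10 in the perturbed library, and values of such short RNAs can rest on about 1 fragment, so these counts say little. Those seen in both included SNORA12 (76.8 against 10.8 FPKM), SNORA57 (136 against 30.9 FPKM) and SNORA73B (51.1 against 8.37 FPKM). Their reads can come from the introns of host genes.

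YAP/TAZ target genes were higher as a list. With the trends on length, GC and level removed the percentile stayed at 99.99, which argues against those trends as the whole cause, although 3 members rather than 10 of the 17 were then higher by 2-fold, with ANKRD1 lower both ways. Fibroblasts mixed into the perturbed library would bring collagen transcripts, and the highest of COL1A1, COL1A2, COL3A1, DCN and LUM there was COL1A1 at 0.0985 FPKM. The members went apart, with ANKRD1, AMOTL2 and CYR61 not higher, so a gain of YAP/TAZ activity is at most a hypothesis. Whether the change may follow from the SMARCA2 and SMARCA4 shift or from another difference between the 2 cell populations, which may be 2 clones, stays open, since each group had 1 library.

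NRF2 target genes were lower as a list, with all 18 below 0 and 4 lower by 2-fold. With the trends removed, 16 were below 0 and the median was -0.50 at percentile 0.31. With the ratios as deposited centred on the -0.11 median of genes at 1 FPKM or more in both libraries, the list's median was -0.62. Neither the trends nor a scale difference of that size therefore accounts for the whole pattern. Lower NRF2 activity in the perturbed cells is a hypothesis, and GCLC, TXN and PRDX1, at 2.81 and 3.18, 715 and 801, and 3023 and 3451 FPKM, differed little. The shift of the SWI/SNF ATPases, a different response to carboplatin and other differences between the 2 populations were not told apart by any test here.

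The longest transcripts were higher in the perturbed library over all levels together. From the least to the most abundant of 5 bins of level, the longest 20% differed from the shortest 20% by 0.53, 0.42, 0.25, -0.09 and -0.31 (log2). Bootstrap bounds across genes were 0.37 to 0.64, 0.26 to 0.58, 0.12 to 0.38, -0.18 to 0.01 and -0.37 to -0.23. A trend on level alone would leave about 0 within a bin. The bins at 0.53, 0.42 and 0.25 therefore argue against it as the whole cause for their genes. The longest were not higher in the other bins, and the rule of this test, which asked for all 5, did not decide. More nuclear RNA in the perturbed library is a candidate explanation that was not decided. With MALAT1 left out, 17 genes listed for nuclear-retained RNA had a median of 0.37 at percentile 99.05 with trends removed. Of these, 4 were higher by 2-fold and 3 were below 0. The 4 higher, DDX17, PNISR, LUC7L3 and ANKRD36, are protein-coding genes, like most of the list, and their FPKM also counts exported mRNA. The long non-coding members went both ways with trends removed: PVT1 0.96, NEAT1 0.37, TUG1 0.19, OIP5-AS1 -0.59 and LINC-PINT -0.72. DDX17 was at 19.5 against 6.27 FPKM, but OIP5-AS1 at 15.9 against 21.6 FPKM and LINC-PINT at 2.27 against 4.04 FPKM. A list member without a known length, LINC00657, is mainly cytoplasmic and was not among the 17. Differences in RNA integrity or cDNA length between the libraries were not tested.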
